A study of Mus musculus with 2 samples.

How the data were processed

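Cells were taken from the small-intestinal lamina propria of C57BL/6 mice after 45 min of clamping of the superior mesenteric artery, the vessel that feeds the small intestine. Per the labels, cells of 20 mice without reperfusion were pooled into 1 library, and cells of 26 mice after 6 h of reperfusion into the other. Dead cells were removed and magnetic beads against CD4 enriched the suspensions, per the design text of the series. The protocol text of the labels names beads against CD11b or CD4, and the design text was followed. Cells were fixed for 19 h at 4 °C and measured with a probe-based assay for fixed cells, in which pairs of gene-specific probes are ligated on the RNA and counted, so a gene is read only where its probes bind.

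The deposited values are raw counts, whole numbers of unique molecular identifiers (UMIs) per gene and cell barcode, with no normalization. The authors made them with Cell Ranger 7.1.0 and genome build mm10, per the submitters' processing notes. The probe set, the Cell Ranger settings and any further filter were not given in the sources used here. The matrices held 19059 genes, 9126 barcodes at 0 h and 6010 at 6 h. UMIs summed to 80856231 at 0 h and 36291433 at 6 h, with medians of 4781 and 3745 per barcode. The 5th and 95th percentiles were 810 and 31665 UMIs at 0 h and 732 and 18827 at 6 h. Gene positions came from the GENCODE annotation (release M21) of GRCm38, the assembly that mm10 denotes. Not analysed here were 15 symbols of the fixed gene and marker lists that had no match among the measured genes: Aldoa, Ccnb1, Cx3cr1, Defa24, Ear2, Eno1, Gapdh, Gpx4, Ly6c1, Ly6c2, Mx1, Trdv4, Tsix, Xist and Zfp36l1.

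Cells were kept with at least 200 genes and under 10% of UMIs from mitochondrially encoded genes. At 0 h, 1 barcode failed the gene minimum and 49 the mitochondrial limit. At 6 h, 1 and 9 failed. Scrublet, run per library within scanpy, called 1 doublet of 9076 cells at 0 h and 0 of 6000 at 6 h. At that rate the caller has most likely not worked, so doublets were not effectively removed here. Whether doublets had been removed before deposit was not stated in the sources used here. Analysis went on with 9075 and 6000 cells. Counts per 10000 were log-transformed, and 2000 variable genes were chosen, leaving out the fixed response lists. Cells of both libraries were clustered together without integration (30 principal components, 15 neighbours, Leiden resolution 1, 2 iterations, seed 0). CD4 T-like cells were clustered again the same way. Tools were scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 in Python 3.11.15, and edgeR 4.0.16 for TMM factors.

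Clusters were called X-like from marker lists. A cluster took the class whose markers scored highest. It stayed without a name with fewer than 3 detected markers, with more markers of another class among its top 10 genes, or with a low UMI count and no own marker among them. A class was compared between libraries only where none of its clusters had more top genes from another class than from its own, leaving out genes within 1.5-fold across clusters. The scoring rule and that 1.5-fold limit were written after clusters and their counts per library had been seen. The naming went through 3 versions, and version 2 is the one used. A run with Leiden until stable and version 3 was briefly the main one and was then set aside; it is among the alternatives, and its naive T cell share moved in the opposite direction.

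Shares of cells carry exact (Clopper-Pearson) 95% binomial intervals. A share of 0 is given with the limit of 3 counts. Counts were summed per library and class and scaled to counts per 1000000 UMIs (CPM), and log2 ratios of 6 h over 0 h used a pseudocount of 5 CPM on both sides, which understates differences of low genes. Ratios of CPM carry exact conditional binomial 95% intervals. All intervals cover counting error only. With 1 library per group no test was made, no p-value is given, and differences between the libraries have no replicate check. The size rule was a mean CPM of at least 20 and a log2 ratio of at least 1 or at most -1 over all CD4 T-like cells. Within a class it was a mean CPM of at least 50, in classes of at least 100 cells per library. For each of 29 gene lists the median log2 ratio was set among 10000 random lists of equal size, matched on mean CPM in 20 bins. A percentile of such a median describes these libraries and is not a test of the condition. For shares of cells with a UMI, each cell was thinned at random to 1600 UMIs, the 10th percentile of CD4 T-like cells rounded down, and shallower cells were left out. B-like cells, thinned alike, gave the background for T cell genes.

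Genes were named by a fixed rule: the 10 highest and 10 lowest log2 ratios in CD4 T-like cells, up to 4 members per list with the largest ratio in the direction of the list's median, a set of single genes of T cell identity and function, and the 3 highest and 3 lowest within each class. Leading genes of a cluster only say what it is. The filters, clustering settings, markers, gene lists, size rules, naming rule for genes and all but 9 of the alternatives were fixed before the data were examined.

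Those alternatives covered the cell filter, doublets, clustering genes, resolution, components, depth, scaling (TMM and median-of-ratios), pooling, pseudocount, expression minimum, weighting of classes, and a UMI gate for CD4 T cells (a UMI of Cd4 and of a CD3 chain or Trac). After the data were seen, 9 more were added, on naming, Leiden seeds and iterations, and high doublet scores.

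The ratio and list steps were tested on simulated data for the comparison in CD4 T-like cells, over 6810 genes. The size rule took 91 of 91 genes simulated at 3-fold, 0 of 96 at 1.5-fold and 0 of 6591 unchanged genes. Intervals held the simulated ratio for 94.9% of genes, and 1 of 29 lists fell outside its 95% range. The simulated counts were independent draws, as the intervals assume, without spread between cells or libraries. They check the steps and not how well the intervals hold for real UMIs, which can lie in a few cells. Thinning brought simulated shares of 71.7% and 44.5%, which differed by depth alone, to 27.8% and 29.1%.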

Results

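Single-cell counts of unique molecular identifiers (UMIs) were obtained from lamina propria cells of the mouse small intestine, enriched on CD4 beads, after 45 min of arterial clamping. Of the 2 libraries, 1 pooled 20 mice at 0 h of reperfusion and 1 pooled 26 mice at 6 h, so each time point was n = 1 and no difference could be set against a spread between replicates. After filtering, 9075 cells at 0 h had a median of 4805 UMIs and 6000 cells at 6 h a median of 3747. The CD4 T-like cells numbered 5194 and 3276, with medians of 4288 and 3381 UMIs and sums of 35900198 and 13175966 UMIs. The comparison of 0 h with 6 h bears on the question in the series title, namely which CD4 T cells are present in an organ shortly after ischemia and what they express.

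Neutrophil-like cells, which carried S100a8 and S100a9 as leading genes, made up 1.26% of cells at 0 h (114 cells; 95% interval 1.04 to 1.51%) and 11% at 6 h (660 cells; 10.2 to 11.8%), a ratio of shares of 8.76 (7.17 to 10.8). Eosinophil-like cells were also a higher share, 0.132% at 0 h (12 cells) and 0.683% at 6 h (41 cells), a ratio of 5.17 (2.66 to 10.8). Group 3 innate lymphoid and lymphoid tissue inducer-like cells, which produce interleukin 22 in the gut wall, were 6.24% at 0 h and 2.78% at 6 h, a ratio of 0.446 (0.373 to 0.531). Plasma cell-like cells were 3.06% and 1.5%, a ratio of 0.490 (0.382 to 0.623), and endothelium-like cells 3.16% and 1.55%, a ratio of 0.490 (0.384 to 0.621). Fibroblast-like cells had a ratio of 0.263 (0.168 to 0.398) and plasmacytoid dendritic cell-like cells 0.504 (0.350 to 0.714). CD4 T-like cells were 57.2% at 0 h (56.2 to 58.3%) and 54.6% at 6 h (53.3 to 55.9%), a ratio of 0.954, but the ratio lay above 1 under 4 alternative settings, so no direction was read. The UMI gate for CD4 T cells held 4383 of 9075 cells at 0 h and 1861 of 6000 at 6 h, a lower share at 6 h. Cells were not thinned for this gate, and shares of cells with a UMI move with depth, which was lower at 6 h.

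Macrophage-like cells were 11.3% and 8.60% of cells, a ratio of 0.764 (0.686 to 0.850), and different clusters held them at the 2 time points. Cluster 13, led by Gbp2b, C6 and the macrophage receptor Adgre1, had 634 cells at 0 h and 104 at 6 h. Cluster 18, led by Ccl12, the haemoglobin scavenger receptor Cd163 and Lyve1, had 338 cells at 0 h and 0 of 6000 at 6 h, which allows a share of up to 0.05%. Cluster 14, led by the growth factor Pgf and the matrix metalloproteinases Mmp13 and Mmp12, had 50 cells at 0 h and 412 at 6 h. With 1 library per time point, each of these clusters may stand for a library and not for a cell type. B-like cells had a ratio of 0.915 (0.806 to 1.04), group 2 innate lymphoid-like cells 1.10 (0.838 to 1.43), natural killer-like cells 1.06 (0.659 to 1.69) and epithelium-like cells, led by Muc6, Tff2 and Gkn3, 1.18 (0.784 to 1.76), all with intervals that held 1. Bead enrichment for CD4 sets all of these shares, which say nothing of cell numbers in the tissue, and the libraries also differed in depth.

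**Figure D1:**
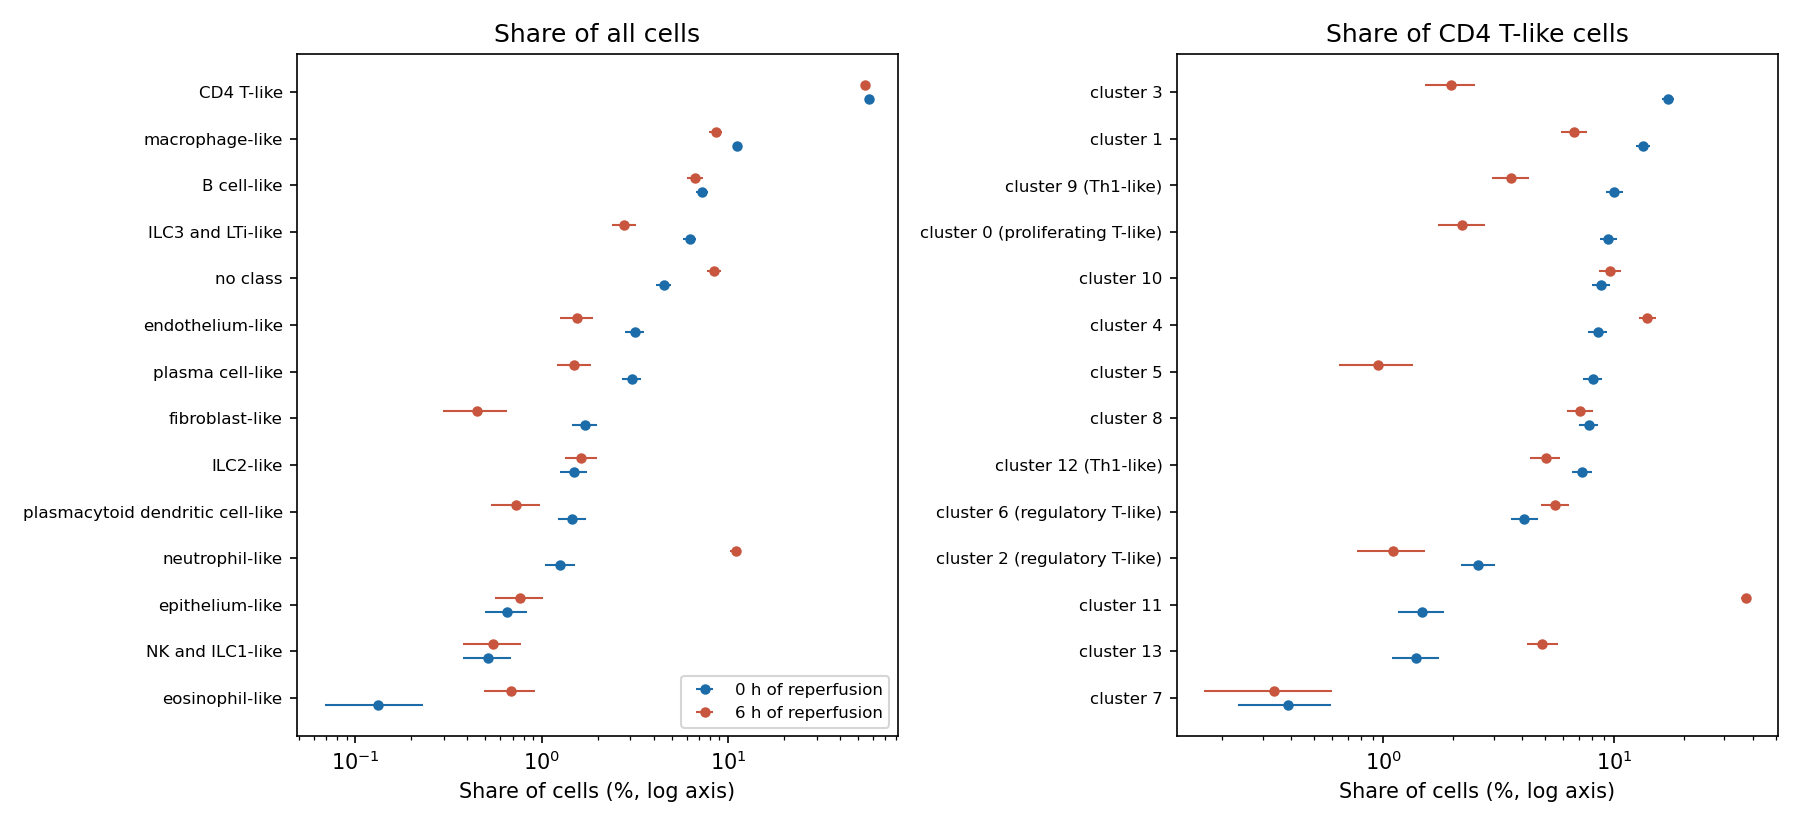
Shares of cells (%, log axis) at 0 h (blue) and 6 h (red), for each class among all cells (left) and for each cluster among CD4 T-like cells (right); points are the shares of 1 library each, bars are exact 95% binomial intervals, and names on the right stand only where a class could be compared. The neutrophil-like share was 1.26% at 0 h and 11% at 6 h, and T cell cluster 11 was 1.46% and 37.1%.

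Within the CD4 T-like cells, Th1-like cells were 17.3% at 0 h (16.2 to 18.3%) and 8.61% at 6 h (7.67 to 9.62%), a ratio of 0.499 (0.435 to 0.571). They comprised cluster 9, led by Ccl5, Gzmk and Itga1, with a ratio of 0.357 (0.289 to 0.437), and cluster 12, led by Zbtb16, Xcl1, Ifng and Tbx21, with a ratio of 0.696 (0.576 to 0.838). Cluster 12 had as many leading genes of gamma-delta T cells, such as Trdc, as of Th1 cells. Proliferating T-like cells, led by the cyclin Ccna2, Mki67 and Birc5 together with Il17a and Il22, were 9.41% (8.63 to 10.2%) and 2.20% (1.72 to 2.76%), a ratio of 0.233 (0.180 to 0.299). In the 13 alternative runs that separated both a Th17-like and a proliferating class, the latter was smaller, at 3.51 to 6.43% at 0 h (median 3.69%) and 0.479 to 1.37% at 6 h (median 1.08%). Regulatory T-like cells were 6.66% and 6.65%, a ratio of 0.999 (0.839 to 1.19), which held a ratio of 0.426 (0.286 to 0.619) in cluster 2, led by Lrrc32 and Eomes, and of 1.36 (1.11 to 1.67) in cluster 6, led by Il10 and Foxp3. The regulatory T ratio ran from 0.521 to 1.54 over alternative settings and carries no direction. Type 1 genes were also lower inside the Th1-like class (median log2 ratio -0.34), whose mix of clusters 9 and 12 differed between the libraries.

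The classes scored as naive and follicular helper T cells failed the comparability check, so their clusters are given by number. Clusters 7, 10, 11 and 13 had more leading genes of another class than of their own. Clusters 1, 3, 4 and 5 passed the check themselves. Clusters 3 and 5, both led by Pdlim4 and with Dapl1 (cluster 3) or Klf2 (cluster 5) next among their leading genes, held 17.1% and 8.07% of CD4 T-like cells at 0 h and 1.95% and 0.946% at 6 h. Cluster 11, led by Neb, Ndrg3, Abca1 and Ttyh3, held 76 cells (1.46%) at 0 h and 1215 (37.1%) at 6 h. Its leading genes are also among the highest genes of the whole 6 h pool, so its size is not a comparison of a cell type, and clusters 3, 5 and 11 may be the library. Cluster 1, led by Tnfsf8 and Tbc1d4, was 13.3% and 6.68%, cluster 4, led by Plaur and Ccr7, 8.47% and 13.9%, cluster 10, led by Hspa4l and Spry1, 8.78% and 9.62%, and cluster 13, led by Astl, 1.39% and 4.88%. Cluster 7, with 20 and 11 cells, was led by the immunoglobulin genes Igkc and Igha, and cluster 8, with 7.76% and 7.11%, had low UMI counts and no name. A Th17-like class separated in 14 of 17 alternative runs, with median shares of 4.16% at 0 h and 0.378% at 6 h, and not in the main one.

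Counts were summed over all CD4 T-like cells to ask which genes differed between 0 h and 6 h. Of 6810 genes with a mean of at least 20 counts per 1000000 UMIs (CPM), 33 were at least 2-fold higher at 6 h and 135 at least 2-fold lower. The highest was Neb, which encodes the muscle filament protein nebulin (chromosome 2, 52136647 to 52378474 of GRCm38, minus strand), at 20.8 CPM at 0 h and 178 at 6 h, a log2 ratio of 2.83 and a ratio of 8.58 (7.89 to 9.32). The neutrophil calprotectin genes S100a9 (16.3 and 94.2 CPM, log2 ratio 2.22) and S100a8 (10.6 and 46.1 CPM, 1.71) came next with the cholesterol exporter Abca1 (1.74). The Wnt co-receptor Lrp5 (1.51), Ndrg3 (1.45), the neutrophil granule enzyme Mpo (1.41), Ttyh3 (1.35), the urokinase receptor Plaur (1.32) and the cytokine Il11 (1.29) followed. In B-like cells, not a known source of calprotectin, S100a9 was at 5.17 CPM at 0 h and 101 at 6 h.

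The lowest gene was Il22, which encodes the epithelial barrier cytokine interleukin 22 (chromosome 10, 118204942 to 118210047, plus strand), at 56.4 CPM at 0 h and 4.78 at 6 h, a log2 ratio of -2.65 and a ratio of 0.0847 (0.0649 to 0.109). Il17a, the lead cytokine of type 17 cells, was at 144 and 33.5 CPM (log2 ratio -1.95; ratio 0.233, 0.211 to 0.256). The interleukin 1 receptor Il1r1 had a log2 ratio of -2.16, the shared interleukin 12 and 23 receptor chain Il12rb1 -2.03, the granule gene Nkg7 -1.95 and Podnl1 -1.82. Thy1, a surface protein of T cells, was at 690 and 177 CPM (-1.93), and the invariant CD3 chain Cd3e at 835 and 465 CPM (-0.84). Plasma cell transcripts were also among the 10 lowest, with Igkc at 1148 and 185 CPM (-2.60), Igha at -2.58 and Jchain at -2.19. T cell cluster 7, with 20 cells at 0 h, held 51.1% of the Igkc, 47.0% of the Igha and 39.6% of the Jchain UMIs of the 0 h pool, and without it the log2 ratios were -1.61, -1.69 and -1.51. T cell transcripts were lower at 6 h in B-like cells too, with Cd3e at 110 and 11.5 CPM and Thy1 at 72.4 and 3.37. Plasma cell transcripts went both ways in other classes: Igkc was at 384 and 141 CPM in macrophage-like but at 467 and 2676 in neutrophil-like cells, and Igha at 197 and 334 CPM in B-like cells. With T cell classes given equal weight in both libraries, 22 genes instead of 135 were at least 2-fold lower, and Il17a moved to -0.80 and Thy1 to -1.18. Genes outside the response lists could shape these classes, so part of such a shrinkage may arise by construction. The weighting also used the naive-like and follicular helper-like classes, which failed the comparability check.

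Genes of memory-phenotype T cells were lower at 6 h, with 20 of 21 measured members below 0, 7 of them at least 2-fold, and a median log2 ratio of -0.82, below the median of each of 10000 matched random lists. The activation and memory marker Cd44, a receptor for hyaluronan, was at 206 CPM at 0 h and 95.9 at 6 h (ratio 0.466, 0.439 to 0.495). The galectin Lgals1 had a log2 ratio of -1.62, the annexin Anxa2 -1.56, S100a4 -1.52 and S100a6 -1.38, while Il2rb was at -0.60 and the interleukin 7 receptor Il7r at 0.11. Tissue residency genes had a median of -0.51, with 5 of 19 at least 2-fold lower, namely the chemokine receptors Cxcr6 (-1.62) and Ccr9 (-1.63), the aryl hydrocarbon receptor Ahr (-1.30), Xcl1 (-1.30) and P2rx7 (-1.03, picked after its value was seen), and with Itgae at -0.62 and Cd69 at -0.14. Trafficking receptors and integrins had a median of -1.18 (-1.03 with Leiden seed 1), with 13 of 15 members below 0 and 8 at least 2-fold lower, among them Cd226 (-1.39), Cxcr3 (-1.36) and the gut-homing integrin chain Itgb7 (-1.20, with its partner Itga4 at -0.45). With T cell classes weighted alike the medians shrank to -0.22 for memory-phenotype, -0.25 for residency and -0.51 for trafficking genes. Genes of these lists could shape those classes, so part of the shrinkage may arise by construction. The residency median lay inside its random range under the first naming version (-0.16).

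Recirculation and lymph node homing genes had a median of 0.09, inside the range of random lists (percentile 76.8), with 9 of 15 members above 0. Ramp3 was at 0.83 and Arhgef18 at 0.79. The sphingosine receptor S1pr1 was at -0.02 and its regulator Klf2 at -0.07. Naive T cell genes had a median of 0.01 (percentile 43.9), with Treml2 at 0.68 and the transcription factor Bach2 at 0.62. With T cell classes weighted alike, the naive median moved to -0.23.

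All 14 measured genes of the type 17 helper programme were below 0 at 6 h, 7 at least 2-fold, with a median of -1.11. Besides Il22 and Il17a they included Il17f (log2 ratio -1.68) and Ccr6 (-1.31). The interleukin 23 receptor Il23r, below the expression minimum, was at -1.65. All 16 genes of the type 1 helper programme were below 0, 7 at least 2-fold, with a median of -0.77. Its signature cytokine Ifng was at 279 and 120 CPM (-1.19; ratio 0.430, 0.407 to 0.453), the lineage regulator Tbx21 at 156 and 101 CPM (-0.60), Il12rb2 at -1.61 and Il18r1 at -0.62. Effector cytokines and chemokines had a median of -0.30, with 7 of 18 at least 2-fold lower and 1 at least 2-fold higher, the chemokine Ccl3 (1.17, picked after its value was seen), and with Tnf at -0.28. Csf2 (0.16), Il2 (-0.31), Il4 (-0.34) and Il13 (0.13) lay below the expression minimum. The type 2 programme had 4 measured genes with a median of 0.03 (percentile 65.7), among them its lineage regulator Gata3 at 0.03 and the receptor Ccr8 at 0.43, and the follicular regulator Bcl6 was at 0.05. With classes weighted alike, the medians were -0.41 for type 17, -0.32 for type 1 and -0.14 for effector genes. Type 1 and type 17 genes are also markers by which the classes were named, so part of that shrinkage may arise by construction.

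The regulatory T cell programme had a median of -0.45 (percentile 0.04), with 11 of 15 members below 0, among them Capg (-1.08), Izumo1r (-0.72) and the inhibitory receptor Ctla4 (-0.61). Its master regulator Foxp3 was at 36.4 and 52.7 CPM (0.48; ratio 1.45, 1.32 to 1.59) and the cytokine Il10 at 0.16. With classes weighted alike the median was -0.12, inside its random range, in classes named partly by these same genes. Co-inhibitory genes had a median of -0.20 (percentile 9.48) with Cd160 at -1.10. Cytotoxic genes had a median of -0.31 (percentile 3.74), with Nkg7 and the cathepsin Ctsw (-1.73) at least 2-fold lower and granzyme Gzmb at -0.95. Innate cytokine receptors had a median of -0.12 (percentile 9.71), although 4 of 19, Il1r1, Il12rb1, Il12rb2 and Il18rap, were at least 2-fold lower.

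S phase genes had a median of -0.86, with 17 of 19 below 0 and 7 at least 2-fold lower, among them the nucleotide synthesis genes Rrm2 (-1.51), Dut (-1.30) and Tyms (-1.23). All 17 G2/M genes were below 0, 7 at least 2-fold, with a median of -0.91, led by Mki67 (147 and 44.3 CPM, -1.63), Birc5 (-1.57), Ube2c (-1.55) and Ccna2 (-1.49). Oxidative phosphorylation genes had 30 of 31 members below 0, none at least 2-fold, with a median of -0.48, and mitochondrially encoded genes 12 of 13 with a median of -0.38, for example Ndufb9 (-0.98), Ndufc2 (-0.80), mt-Nd2 (-0.72) and mt-Co1 (-0.54). Cells thinned to equal depth gave medians of 0.01 for G2/M genes, -0.21 for S phase genes and -0.24 for oxidative phosphorylation genes, and unthinned cells weighted alike -0.10, -0.25 and -0.27. Mitochondrially encoded genes did not shrink, with -0.43 in thinned cells and -0.52 in unthinned cells weighted alike, and over all barcodes the median share of UMIs from these genes was 0.570% at 0 h and 0.392% at 6 h. With classes weighted alike the medians of G2/M, S phase and oxidative phosphorylation genes were -0.08, -0.26 and -0.14, and that of mitochondrially encoded genes -0.37.

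Stress and activation lists stayed inside the range of random lists. Immediate early genes had a median of 0.16 (percentile 77.8) with 15 of 17 above 0, among them Ier5 (631 and 1051 CPM, 0.73), Ier3 (0.69) and Fosl2 (0.50), and with Fos at 0.16. Heat shock genes had a median of 0.08 (percentile 59.2), with the inducible chaperones Hspa1a at 1318 and 2200 CPM (0.74) and Hspa1b at 0.63. Glucocorticoid responsive genes had a median of 0.14 (percentile 90.9), with Pik3ip1 at 0.81 and the metallothioneins Mt2 at 0.58 and Mt1 at 0.55. Hypoxia and glycolysis genes had a median of -0.14 (percentile 4.21; Mif -1.0, Pgk1 -0.96, Tpi1 -0.95), oxidative stress genes -0.18 (percentile 4.78; Gsr -0.75, Txn1 -0.75) and unfolded protein response genes -0.11 (percentile 8.72; Sdf2l1 -1.45, Pdia4 -0.76). T cell receptor activation genes had a median of -0.11 (percentile 4.30; Icos -0.66, Cd40lg -0.49, Nr4a1 0.19) and NF-kB targets 0.11 (percentile 74.1; Bcl3 0.62, Birc3 0.29). STAT feedback genes had a median of 0.06 (percentile 67.4; Pim2 0.44), interferon stimulated genes 0.03 (percentile 80.6; Irf9 0.55, Stat2 0.44), p53 and apoptosis genes 0.01 (percentile 50.6; Bcl2l11 0.82, Gadd45a 0.53, with Bak1 at -1.11, picked after its value was seen) and sex-linked genes 0.15 (percentile 84.3; Ddx3y 0.33, Eif2s3y 0.27).

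**Figure D2:**
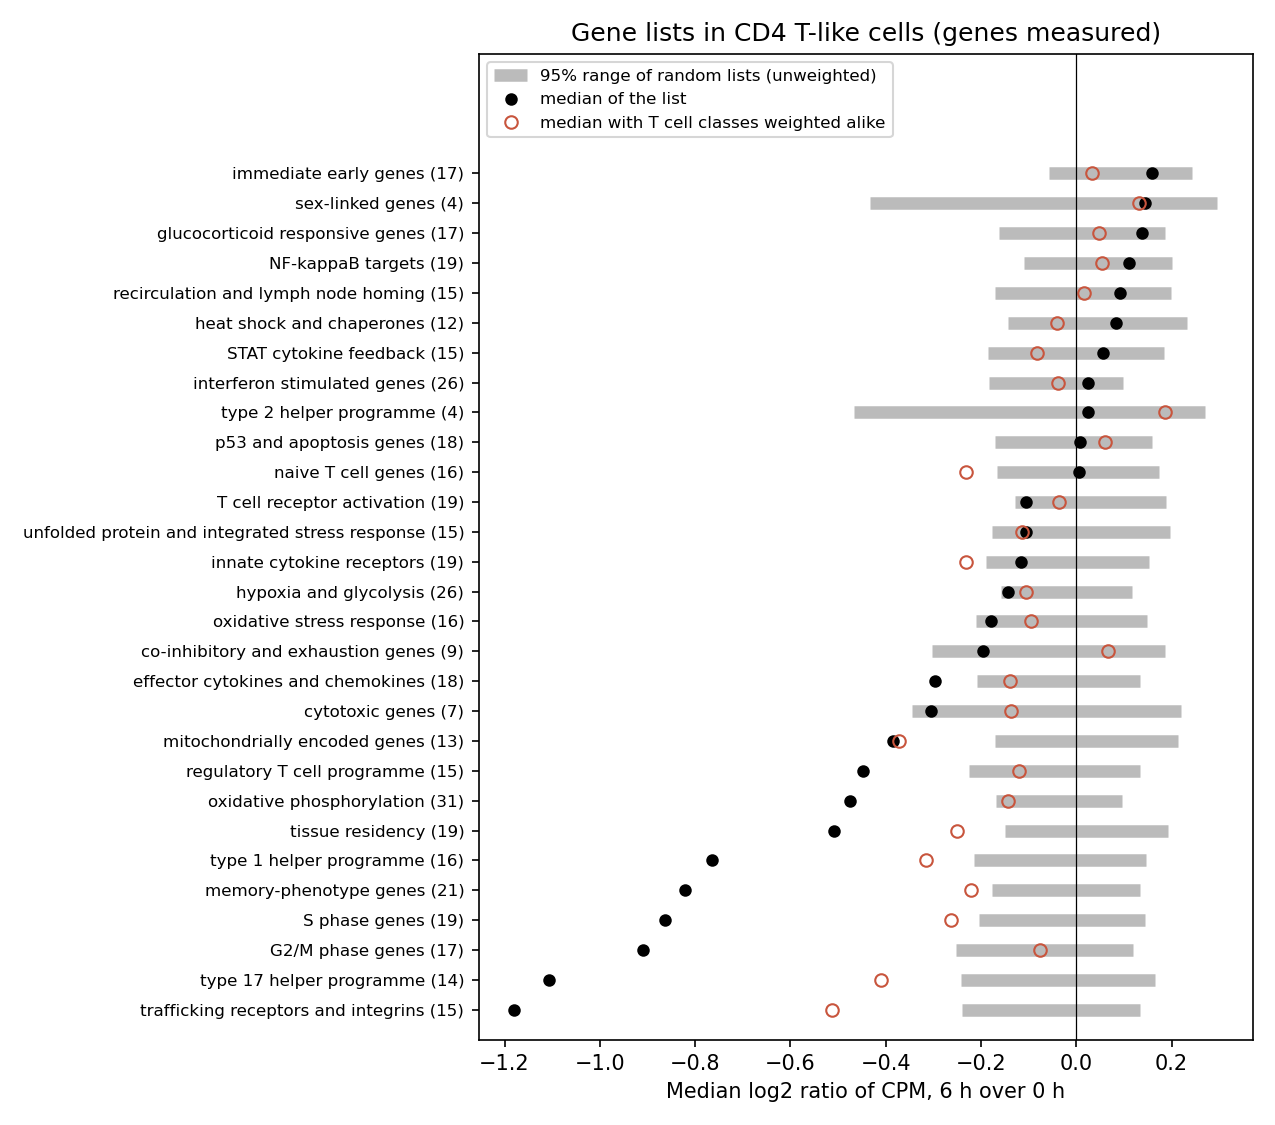
Median log2 ratio of CPM, 6 h over 0 h, of each gene list in CD4 T-like cells (black; measured genes in brackets), with the 95% range of matched random lists (grey bar) and the median with T cell classes weighted alike (open red), from 1 library per time point. The trafficking list lay at -1.18 and moved to -0.51 with classes weighted alike. Genes outside the response lists could shape these classes, so part of such a shift may arise by construction.

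Shares of CD4 T-like cells with a UMI were compared after thinning to 1600 UMIs, which left 4678 cells at 0 h and 2950 at 6 h and left out 516 and 326. Ifng was seen in 14.7% of cells at 0 h (13.7 to 15.7%) and 6.03% at 6 h (5.20 to 6.95%), against 1.43% and 0 of 376 (up to 0.798%) in B-like cells. Tbx21 was seen in 16.7% and 9.19% (B-like 2.39% and 3.72%), Il17a in 3.08% and 0.746% (0.318% and 0 of 376, up to 0.798%) and Il22 in 2.46% and 0.237% (0.318% and 0 of 376, up to 0.798%), so that neither 6 h share was shown to lie above the background. Cd44 was seen in 21.2% and 11.2%, with 12.1% and 7.71% in B-like cells, where it is also expressed. Tnf was seen in 27.9% and 23.0% (11.8% and 6.12%) and Cd69 in 72.8% and 66.7% (58.4% and 51.9%). Foxp3 (3.21% and 3.29%), Il10 (3.51% and 3.69%), Gata3 (31.3% and 31.1%) and Ccr7 (43.2% and 44.8%) had overlapping intervals. Mki67 was at 4.57% and 1.83%, with 1.27% and 2.39% in B-like cells, which can also divide and give no background for it. Il17f was at 2.12% and 1.32%, and its 6 h value lay at the B-like background (1.06%). Il2 (0.620% and 0.169%), Il4 (1.37% and 0.780%), Csf2 (0.705% and 0.407%) and Il13 (0.449% and 0.881%) were rare, with 6 h shares of Il2 and Csf2 also under that limit of 0.798%, and the order of Il13 turned without thinning.

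Without thinning, at median depths of 4288 and 3381 UMIs, Ifng was at 21.0% and 8.49% (B-like 3.17% and 0.499%), Tbx21 at 28.7% and 14.3% (8.14% and 6.23%), Il17a at 4.68% and 1.01% (0.452% and 0 of 401, up to 0.748%) and Il22 at 5.78% and 0.580% (0.905% and 0 of 401, up to 0.748%). Cd44 was at 42.0% and 20.5% (26.8% and 16.7%), Tnf at 49.7% and 37.5% (25.5% and 10.5%), Cd69 at 83.8% and 77.6% (76.3% and 64.8%) and Gata3 at 55.8% and 47.8% (6.49% and 4.24%). Foxp3 was at 6.87% and 5.74% (0.452% and 0.499%), and Mki67 at 9.88% and 3.72% (3.62% and 3.24%). The 6 h share of Mki67 lay near the B-like one, which is no background for a cell cycle gene, since B cells can divide too. B-like cells had median depths of 4222 and 3323 UMIs, and thinning left 628 and 376 of them.

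Within the Th1-like class, 22 of 4136 genes with a mean CPM of at least 50 were at least 2-fold higher at 6 h and 81 at least 2-fold lower. The neutrophil-attracting chemokine Cxcl2 was highest, at 12.2 and 173 CPM (log2 ratio 3.37; ratio 14.1, 10.3 to 19.8), followed by S100a9 (3.27) and Ctla2a (2.14). The gut-homing receptor Ccr9 was lowest, at 191 and 39.9 CPM (-2.13; ratio 0.208, 0.149 to 0.285), followed by Il12rb1 (-2.03) and the residency regulator Zfp683, also known as Hobit (-2.03). Ifng was at 1421 and 1144 CPM in this class (-0.31), a smaller difference than in the whole pool. The trafficking list had a median of -0.94 and the memory-phenotype list -0.48, both below each of the random lists, and the type 1 list -0.34 (percentile 0.06). Cluster 9 held 520 of the 896 cells of this class at 0 h and 117 of 282 at 6 h, and cluster 12 held 376 and 165. All values of the class, that of Ifng included, thus compare different mixes of its clusters. In cluster 9, Cxcl2 (3.58) and Plaur (3.31) were highest and Ctsw (-2.65) and Tesc (-2.64) lowest. In cluster 12, S100a9 (3.47), Cxcl2 (3.24) and the chemokine Cxcl10 (1.87) were highest and Zfp683 (-2.35) lowest.

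Within the regulatory T-like class, 13 of 4226 genes were at least 2-fold higher and 21 at least 2-fold lower. The highest were S100a9 (4.60 and 105 CPM, log2 ratio 3.52), Ctla2a (137 and 833 CPM, 2.56; ratio 6.06, 5.30 to 6.94) and the metal-binding metallothionein Mt2 (1.78), and the lowest Igha (-2.09), Eomes (-1.97) and S100a4 (-1.71). Cluster 2, led by Eomes among others, held 134 of the 346 cells of this class at 0 h and 36 of 218 at 6 h, so these values compare different mixes of its clusters. In its cluster 6, Ctla2a (2.45) and Mt2 (1.72) were likewise among the highest, and Ifng was at 123 and 10.5 CPM (-3.05) and Ccl5 at 101 and 11.7 (-2.68). In cluster 1, Il17a was at 17.4 and 90.2 CPM (2.09; ratio 5.18, 4.05 to 6.61), opposite in direction to the whole pool. Its 131 UMIs at 6 h came from at most 33 cells, the number of all CD4 T-like cells with an Il17a UMI then. The interval treats these UMIs as independent. Cluster 0, led by Il17a among others, held 489 and 72 cells, so the direction may reflect where the few Il17a cells were clustered, which was not tested. In cluster 1, Gzmb (-2.32), Ctsw (-1.91) and Nkg7 (-1.82) were lowest. Neb was among the 3 highest genes in clusters 1 (2.54), 4 (2.53), 8 (2.70) and 10 (3.16), and Thy1 was lowest in clusters 4 (-1.94) and 10 (-1.53). These values come from 1 library per time point, and S100a9 was higher in B-like cells too (3.38).

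Among the other classes, macrophage-like cells had 302 of 3708 genes at least 2-fold higher at 6 h and 284 lower (556 and 149 with TMM scaling). Saa3, an acute-phase serum amyloid gene, was at 0.948 and 591 CPM (log2 ratio 6.65), Pgf at 24.4 and 828 (4.82) and the secreted protease Htra1 at 7.86 and 334 (4.72). The haemoglobin chains Hbb-bs (192 and 0.156 CPM, -5.26) and Hba-a2 (-4.45) were lowest with Thy1 (-3.95). Neutrophil-like cells had 152 of 2408 genes higher and 233 lower (384 and 74 with TMM), with the chitinase-like gene Chil3 at 31.0 and 1615 CPM (5.49), the lipase Lipg at 4.16 and the plasma cell transcript Igkv8-27 at 5.95, and with the T cell genes Cd5 (-4.34), Thy1 (-4.30) and Dtx1 (-4.00) lowest. TMM moved the median of all genes from -0.04 to 0.28 in macrophage-like and from -0.21 to 0.35 in neutrophil-like cells, so single values there shift by that much with the scaling. Macrophage-like cells also lay in different clusters at the 2 time points, with Pgf leading cluster 14 and Hbb-bs among the leading genes of cluster 18, so their values compare different clusters and not 1 fixed population.

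B-like cells had 8 of 4193 genes at least 2-fold higher and 23 lower, with S100a9 (3.38), the glucocorticoid-induced chaperone Fkbp5 (34.4 and 124 CPM, 1.71) and Mt1 (1.68) highest and the T cell genes Cd3e (-2.81), Trbc2 (-2.49) and Il2rb (-2.33) lowest. Group 3 innate lymphoid-like cells had 27 of 4352 genes higher and 71 lower, with S100a9 (2.84), Tmtc2 (2.21) and the signalling inhibitor Spry2 (125 and 426 CPM, 1.73) highest and Ly6a (397 and 18.4 CPM, -4.10), Apoe (-2.73) and Cd3g (-2.68) lowest. Transcripts of other cell types, such as T cell genes in B-like cells, were thus among the lowest genes of several classes.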

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

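All 8 tests weighed here were chosen only after the results they measure had been seen, and several replaced earlier versions after values were known. A depth test over all 6 lists together was split into the 2 given here, a test weighting the main T cell classes was replaced by clusters made without the lists' genes, and the B-like test of 8 genes went from excluding to undecided when its counting spread was added. For the same 8 genes a test weighting the main classes, which leaves the mix inside the naive-like class in place (1.34), was replaced by clusters made without them, which were undecided under a first limit of 75% of the size and excluding under the 2-fold size rule used here. The claim that free RNA reached every cell type was first read from B-like cells alone, was contradicted by the table of all classes and became a test of its own, and this was then rewritten so that only a class below CD4 T-like cells counts against it. Both libraries differ in time of reperfusion, mice and pool at once, so no biological explanation was tested, and the time of reperfusion stays open beside each technical one.

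The comparisons of cell classes left out 2 clusters without a name, and both held a higher share of cells at 6 h. Cluster 5 had 285 cells at 0 h (3.14%) and 300 at 6 h (5.0%), a ratio of shares of 1.59 (1.35 to 1.88), with medians of 718 and 697 UMIs and with Gpr137c, Tcta and Fahd1 leading. It went without a name because its UMI counts were low and no marker was among its top genes. Cluster 15 had 126 cells (1.39%) and 208 (3.47%), a ratio of 2.5 (1.99 to 3.14), with medians of 12057 and 9639 UMIs. Its leading genes Cd209a, Chil3, Fn1, Vcan and Ccl22 held markers of dendritic cells and of monocytes, so it took neither name. The cause was not tested for either cluster.

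Genes of the memory-phenotype, type 1, type 17, trafficking, S phase and G2/M lists were lower in CD4 T-like cells at 6 h, with a median log2 ratio of -0.90 over 96 members. For the 60 members outside the cell cycle lists, more UMIs in the cells that carry them is excluded as the whole cause, since cells thinned to equal depth gave -0.89 against -0.90 (counting spread 0.03). For the 36 cell cycle members that account stays open, since thinning moved the median from -0.90 to -0.33. A different mix of T cell states stays open for all 6 lists: in clusters made without these genes and weighted alike the median was -0.34, or 37.7% of its size (spread 0.02). A lower level within the same cells may account for the remainder, and a shift in which cells were recovered may account for the mix.

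S100a8 and S100a9, genes of neutrophils, were higher in CD4 T-like cells at 6 h, when neutrophil-like cells were 11% of cells. At 6 h the S100a8 to S100a9 ratio was 0.490 in CD4 T-like and 0.635 in neutrophil-like cells, a quotient of 0.772 (0.699 to 0.851). This argues against free RNA of exactly the neutrophil-like makeup as the only source. The interval covers counting error only, and the ratio was 0.393 in B-like and 0.477 in macrophage-like cells. Free RNA of mixed sources with a neutrophil part stays open. At 6 h, S100a9 UMIs numbered 288054 in neutrophil-like, 3320 in macrophage-like and 150 in B-like cells. A mix in those proportions would lie near the neutrophil-like ratio, so such a mix would need other proportions or sources. Free RNA that reaches CD4 T-like and B-like cells alike stays open, with a quotient of their S100a9 CPM at 6 h of 0.932 (0.786 to 1.11). Whether it reaches every type alike stays open too: against CD4 T-like cells, plasma cell-like cells were at 0.0686 (0.0391 to 0.112) per UMI and 0.469 (0.267 to 0.765) per cell, epithelium-like cells at 0.319 and 2.53, plasmacytoid dendritic cell-like cells at 0.317 and 0.840, macrophage-like cells at 5.51 and 17 and endothelium-like cells at 7.44 and 26.7, where doublets may add to the high values. Compared with 0 h, S100a9 was not higher in plasma cell-like cells (9.85 and 6.46 CPM; 98 and 16 UMIs) or fibroblast-like cells (75.6 and 72.2 CPM; 91 and 18 UMIs). Its CPM was higher at 6 h in all other classes. These low counts from 1 library per time point do not decide the question. Neutrophils of another makeup that did not pass as cells may be a source, which was not tested.

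The 8 highest genes in CD4 T-like cells at 6 h other than S100a8 and S100a9 were led by Neb and had a median log2 ratio of 1.43. In clusters made without the 8 genes and weighted alike the median was 1.16 (spread 0.05), above the 2-fold size rule, and within the 15 clusters it ran from 0.75 to 1.57. This argues against a different mix of those clusters as the whole cause, though not as part of it. A mix of states inside the clusters stays open, since some lay mostly in 1 library, such as 52 cells at 0 h and 503 at 6 h, or 862 and 84. The 8 genes were also picked as the highest in these same data. A difference between the libraries that acts on every cell type cannot be told apart from one in T cells, because the 8 genes had a median of 0.26 in B-like cells (spread 0.11) and went both ways there, from Neb at 1.81 to Lrp5 at -0.53. A response of the T cells to reperfusion and a difference between the pools or libraries may each explain the 8 genes.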

How the results depend on the processing

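Of the alternatives, 9 were chosen only after the data had been seen: naming versions 1 and 3, Leiden with seeds 1 and 2, Leiden run until stable with 3 seeds, the same with naming version 3, and removal of the 5% of cells with the highest doublet scores. All others were written before the data were examined, and each was run. No paired analysis was possible because the labels number no replicates and each time point is 1 library. For the same reason no result has a test, and a value counts as kept when it moved by less than its 95% counting interval, or a count of genes when it stayed within 1.5 times. Unless a sentence says otherwise, the cause of a move was not tested.

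Shares of most classes kept their direction in every run that gave a value. Ratios of shares ran from 8.68 to 9.42 for neutrophil-like, 4.17 to 6.23 for eosinophil-like, 0.433 to 0.498 for group 3 innate lymphoid-like, 0.488 to 0.542 for plasma cell-like, 0.490 to 0.511 for endothelium-like, 0.263 to 0.286 for fibroblast-like, 0.479 to 0.559 for plasmacytoid dendritic cell-like and 0.756 to 0.804 for macrophage-like cells. Within CD4 T-like cells, Th1-like cells ran from 0.327 to 0.552 over 14 runs and proliferating cells from 0.130 to 0.318 over 15. Medians of the S phase, memory-phenotype, type 1, type 17, trafficking, effector, oxidative phosphorylation and mitochondrially encoded lists lay below their random ranges in 22 of 22 alternatives. The regulatory T programme and the residency list did so in 21, and G2/M genes in 19. These alternatives were not independent. Naming version 3 gave the same numbers of CD4 T-like cells as the run reported, 5194 and 3276. Leiden until stable gave 5252 and 3322 under naming versions 2 and 3 alike. Counts of genes at least 2-fold higher in CD4 T-like cells ran from 11 to 100 and of lower ones from 22 to 204, and stayed within 1.5 times in 15 and 16 of 22.

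A reversal was scored only for list medians outside their random range in the main run and for named genes at least 2-fold apart. For ratios of shares it was scored only where the main interval left out 1. Other lists changed sign without being scored, for example oxidative stress genes (-0.18, up to 0.17) and naive genes (0.01, down to -0.23). So scored, over the alternatives written in advance 247 list medians moved less than their interval, 128 moved more and 1 reversed. For those added later the numbers were 229 kept and 32 moved. For single named genes the numbers were 1267 kept and 461 moved, then 1112 and 114, with none reversed. Part of the kept values could not move: an expression minimum leaves the ratio of a single gene unchanged. Runs with equal numbers of CD4 T-like cells, such as naming version 3 and the run reported, also add little to the kept genes and list medians. Shares of cells in classes were kept 91 times, moved 1 time and reversed 3 times, then kept 108 times and reversed 1 time. Shares of T cell classes among CD4 T-like cells were less stable, kept 21 times and moved 13 times, then kept 37 times, moved 6 times and reversed 1 time. Shares of cells with a UMI of a cytokine or lineage gene were kept 53 times, moved 8 times and reversed 2 times.

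Clustering choices moved the following ratios of shares; the follicular helper-like and naive-like classes, at 0.513 and 1.51 in the run reported, had failed the comparability check and are given for completeness. With the response lists left in, CD4 T-like cells were at 1.001 (reversed), follicular helper-like at 0.626, Th1-like at 0.365, naive-like at 1.36 and proliferating at 0.146. Resolution 1.5 gave 1.02 for CD4 T-like cells (reversed), 0.666 for follicular helper-like, 1.42 for naive-like and 0.130 for proliferating cells, and resolution 0.5 gave 0.353 for Th1-like cells. With 15 components the CD4 T-like ratio was 0.911, the Th1-like 0.327 and the regulatory T-like 1.54. Thinning before clustering gave 1.03 for CD4 T-like cells (reversed), 1.41 for naive-like and 1.24 for regulatory T-like cells.

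Naming version 1 gave 1.09 for CD4 T-like (reversed), 0.659 for follicular helper-like and 0.521 for regulatory T-like cells, with 59 genes higher and 204 lower. List medians under it were -0.16 for residency, -0.86 for memory-phenotype, -0.86 for type 1, -1.33 for type 17, -0.69 for the regulatory programme, -1.05 for S phase, -0.61 for oxidative phosphorylation and -0.35 for mitochondrially encoded genes. Leiden until stable with naming version 3 reversed the naive-like ratio to 0.116, with trafficking at -1.03 and type 1 at -0.64. Seed 1 gave 0.308 for proliferating cells, trafficking -1.03 and type 1 -0.64, and seed 2 trafficking -1.04 and type 1 -0.64. Until stable, trafficking was at -1.03 and type 1 at -0.64 with seeds 0 and 2 alike, and with seed 1 proliferating cells were at 0.318 and type 1 at -0.65. Called doublets, when kept, gave 0.714 for follicular helper-like cells, trafficking -1.04 and type 1 -0.64. Removing high doublet scores gave 0.611 for follicular helper-like and 0.342 for Th1-like cells, with type 1 at -0.65.

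A larger pseudocount shrinks ratios of low genes by construction. At 20 CPM, 11 genes were higher and 73 lower, with medians of -0.40 for residency, -0.84 for trafficking, -0.67 for memory-phenotype, -0.62 for type 1, -0.82 for type 17, -0.70 for S phase, -0.59 for G2/M and -0.41 for oxidative phosphorylation. A pseudocount of 1 CPM gave 58 higher genes, memory-phenotype -0.87, type 17 -1.22 and G2/M -1.08. Changing the expression minimum changes the genes in each list. A mean CPM of at least 5 gave 50 higher genes, trafficking -0.94, type 17 -0.91 and the regulatory programme -0.33. At least 50 gave 17 higher and 82 lower genes, residency -0.13, trafficking -0.94, memory-phenotype -0.67, type 1 -0.60, type 17 -0.85 and G2/M -1.40, and no value for the type 2 list. No minimum gave 52 higher genes, trafficking -0.70, type 1 -0.66, type 17 -0.85 and the regulatory programme -0.33. Within classes, a minimum of 20 CPM gave 31 higher and 41 lower genes in follicular helper-like, 46 and 132 in Th1-like, 49 and 20 in naive-like and 32 and 55 in regulatory T-like cells. The follicular helper-like and naive-like classes had failed the comparability check, so their counts do not compare a cell type.

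Taking CD4 T cells by UMI gate gave 100 higher genes and medians of -0.25 for residency, -0.82 for trafficking, -0.47 for memory-phenotype, -1.23 for type 17, -0.28 for the regulatory programme, -0.65 for S phase, -0.69 for G2/M, -0.36 for oxidative phosphorylation and -0.32 for mitochondrially encoded genes. Classes weighted alike left 22 lower genes and medians of -0.14 for effector, -0.25 for residency, -0.51 for trafficking, -0.22 for memory-phenotype, -0.32 for type 1, -0.41 for type 17, -0.12 for the regulatory programme, -0.26 for S phase, -0.077 for G2/M and -0.14 for oxidative phosphorylation. That weighting may shrink the ratios of genes that shaped the classes partly by construction. TMM and median-of-ratios each gave -0.54 for residency and -0.42 for mitochondrially encoded genes, and moved the median of all genes in CD4 T-like cells from -0.03 to -0.06. In macrophage-like cells TMM gave 556 higher and 149 lower genes, and in neutrophil-like cells 384 and 74, where it shifted the median of all genes from -0.04 to 0.28 and from -0.21 to 0.35.

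Depth limits the shares of cells with a UMI, for which thinning left out 516 and 326 CD4 T-like cells. Cell cycle medians shrank in thinned cells and also, at full depth, with cells or classes weighted alike, so the part of depth in them stays open. The mean over cells of CPM gave 73 lower genes, trafficking -0.99, memory-phenotype -0.70, type 1 -0.91, type 17 -0.84, S phase -0.25, G2/M -0.10, oxidative phosphorylation -0.27 and mitochondrially encoded genes -0.52. Thinned cells gave 87 lower genes, effector -0.38, memory-phenotype -0.71, type 1 -1.02, type 17 -0.83, S phase -0.21, oxidative phosphorylation -0.24 and mitochondrially encoded genes -0.43, and reversed G2/M to 0.0068. Among shares of cells with a UMI, without thinning 0 genes instead of 1 were higher beyond both intervals and Il13 reversed to 0.812, and at the lower thinning depth these were 0 and 0.918.

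Some runs gave no value for a class. Th1-like cells were absent under naming version 1, resolution 1.5 and thinning before clustering, follicular helper-like cells at resolution 0.5 and 15 components, proliferating cells at resolution 0.5 and thinning before clustering, and eosinophil-like cells under the latter. Natural killer-like cells separated among all cells in 3 alternative runs, and in 11 others a natural killer-like cluster lay within the CD4 T-like cells, with 0.521 to 7.52% of them at 0 h and 0.768 to 5.53% at 6 h. Doublets were not effectively removed here, bead enrichment sets the shares, and probes bound what could be counted. With 1 library per time point, reperfusion cannot be parted from differences between the pools, and intervals cover counting error only.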

Other observations

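None of the values in this part comes from a test of an explanation, and the classes and lists given were picked after their values were seen. Macrophage-like cells had a median log2 ratio of 1.48 for oxidative stress genes (percentile 100 among random lists), 0.64 for unfolded protein response genes and -1.26 for heat shock genes, against a median of all genes of -0.04 that TMM scaling moves to 0.28. Group 3 innate lymphoid-like cells had higher medians for T cell receptor activation genes (0.30), NF-kB targets (0.29) and STAT feedback genes (0.31) and lower ones for interferon stimulated (-0.47) and oxidative phosphorylation genes (-0.45). B-like cells had medians of 0.28 for S phase genes, 0.42 for G2/M genes and 0.28 for p53 and apoptosis genes, opposite in sign to the cell cycle lists of CD4 T-like cells.

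Within T cell classes, Th1-like cells had medians of 0.29 for STAT feedback genes, -0.33 for residency, -0.39 for innate cytokine receptors, -0.32 for interferon stimulated, -0.38 for heat shock and -0.50 for mitochondrially encoded genes. Regulatory T-like cells had -0.35 for memory-phenotype genes, -0.49 for naive genes and -0.17 for the regulatory programme. In both classes the mix of clusters differed between the libraries. In T cell cluster 1 the cytotoxic list was at -0.67, the type 1 list at -0.55, trafficking at -0.58 and naive genes at -0.41, and in cluster 4 the naive and trafficking lists were both at -0.46. Naive genes were thus lower within each of these groups, while their median in the whole pool was 0.01. The 2 clusters without a name together held 411 cells at 0 h (4.53%) and 508 at 6 h (8.47%), a ratio of shares of 1.87 (1.64 to 2.13).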
